A study of Mus musculus with 24 samples.

How the data were processed

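Total RNA of 24 sorted hepatocyte populations (8 zones from each of 3 mice aged 3 months, 50000 cells each) was labelled with Cy3 and hybridised to Agilent 1-colour mouse miRNA arrays, per the labels' protocols. The deposited values are intensity values per miRNA, the total gene signal on a linear scale, made with Agilent Feature Extraction per the submitters' processing notes, with the version not given in the sources used here. The other deposited column used was the detection call, 1 or 0 per miRNA and array, per the file headers. In the deposited files a miRNA called undetected had a signal of 0.1 and an error of 1. For detected values the median error given in the files was 11.2% of the signal. No scaling between arrays is recorded in the file headers or labels. No genome build applies, since miRNAs are named by the files. No 2 arrays held identical values. The Pearson correlation of log2 signals between arrays of a zone was 0.901 to 0.977.

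Groups came from the labels, with the mouse number as replicate. Signals of miRNAs, without 21 control sequences, were divided by each array's 75th percentile over the 198 miRNAs detected on all arrays, multiplied by the mean of these percentiles, raised to a floor of 1.12 (the median over arrays of the lowest scaled detected signal) and taken to log2. The 339 miRNAs detected on at least 6 of 24 arrays were tested. For a miRNA undetected on all arrays of a group, the higher group's mean was set against the mean of the lowest detected signals of any miRNA on those arrays. Such a fold is not a lower bound, since the limit of detection can differ between miRNAs. Values at the floor were not ranked. Fits used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05: a moderated F test over zones, the slope on the zone number, zone 8 against zone 1, and a quadratic term. The zone number is a rank and not a distance. A fitted change is the slope over the axis from zone 1 to zone 8, and can differ from the measured difference between these zones where the profile is not a line. All arrays entered 1 fit with no block. Its SEs and p-values leave out the pairing of arrays by mouse, except where the mouse block is named. Tests were two-sided.

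The mouse numbers pair the arrays because the 8 populations of a number came from the same animal. The median correlation of deviations from zone means was 0.610 between arrays of a mouse (lowest 0.254) and -0.394 between mice. The value between mice is drawn negative by the method, since the deviations of the 3 mice in a zone cancel out. Its sign is therefore no property of the mice. In comparisons of whole mice 83 miRNAs were higher and 53 lower in mouse 2 than in mouse 1, 55 and 32 in mouse 3 than in mouse 1, and 69 and 64 in mouse 3 than in mouse 2 (limma). Mouse as a block was an alternative, as were 3 other scalings (the 75th percentile over all miRNAs, which was the same on every array and therefore left arrays unscaled, the summed signal, and quantile normalization), filters at 24 arrays and at 1 array, a floor 4 times lower, eBayes with trend and robust, slide row as a term, 1 slope per mouse, the 6 arrays of zones 1 and 8 alone, and leaving out each mouse or zone. Zone labels were permuted within mice, with counts given for 2 separately seeded sets of 100 draws. Earlier sets were drawn and replaced when the tests were edited.

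The 20 lists of miRNAs were fixed before the data were examined, and the 12 with at least 3 tested members were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Named miRNAs followed a rule fixed at the same time: the 12 largest and 12 most negative slopes among those past the threshold with that sign in all 3 mice, the 5 largest and 5 most negative differences between zones 8 and 1, the 5 largest quadratic coefficients either way, 3 miRNAs past the F test alone, up to 4 members of each list, and the 5 brightest. No miRNA came under the quadratic or the F part. miR-125a-3p, miR-345-5p, miR-221-3p, miR-101a-3p, miR-22-3p, miR-101b-3p, miR-30e-5p, miR-200b-3p and the members of the Dlk1-Dio3 cluster detected in zones 1 to 4 alone fall outside this rule and were named after their values were seen. Gene neighbours were taken from a table of RefSeq genes on GRCm38.p6, in which 333 of 339 tested miRNAs were matched by symbol or synonym.

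The fits were tested on simulated data with the means, mouse effects and residual spread of the 339 miRNAs, in 20 simulations over 24 arrays. Slopes of 0.05, 0.1 and 0.2 per zone were recovered in 12.5%, 46.0% and 79.8% of cases, and with the mouse block in 30.5%, 65.0% and 92.8%. Quadratic coefficients of 0.5 and 1 were recovered in 23.0% and 61.0%, and steps of 0.8 and 1.6 in 30.2% and 65.8%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.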

Results

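MicroRNA levels were measured along the axis of the mouse liver lobule, from the central vein to the portal tract. Hepatocytes of 3 male C57BL/6J mice were sorted by the surface proteins CD73, which is high near the central vein, and E-cadherin, which is high near the portal tract, into 8 populations called zones 1 (most pericentral) to 8 (most periportal). The gates kept viable tetraploid hepatocytes after removal of cells carrying CD45 or CD31. Each of the 24 arrays held the RNA of 1 zone of 1 mouse, so each zone had 3 arrays. The summed miRNA signal of an array lay between 57935 and 138301 intensity units, and between 248 and 368 of the 1881 mouse miRNAs on an array were called detected. The number of arrays limits the precision of every comparison. The 8 arrays of a mouse shared a slide of their own, so mouse and slide were the same factor. On all 3 slides zones 1 to 4 lay in the first row and zones 5 to 8 in the second, so zone and position on the slide cannot be told apart.

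The slope on the zone number asked which miRNAs rise or fall from the pericentral to the periportal end. Levels of miR-31-5p, miR-31-3p, miR-125a-5p and miR-802-5p were not detected on any of the 12 arrays of zones 1 to 4 and were detected on all 12 arrays of zones 5 to 8. The other arm of the miR-125a precursor, miR-125a-3p, was detected on all 12 arrays of zones 1 to 4 and all 12 of zones 5 to 8. Its slope was 0.065 log2 units per zone, against 0.792 for miR-125a-5p. Set against the lowest detected signals of any miRNA on the zone 1 arrays, miR-31-5p was 62.3-fold higher in zone 8. On that measure miR-125a-5p was 15.6-fold, miR-31-3p 14.2-fold and miR-802-5p, a miRNA known to act on hepatic glucose metabolism, 11.7-fold higher. These folds are not lower bounds, since the limit of detection can differ between miRNAs. let-7e-5p, whose gene neighbours that of miR-125a, was detected on 4 of the 12 arrays of zones 1 to 4 and on all 12 of zones 5 to 8. Its log2 signal was 0.50 ± 0.58 in zone 1 and 4.23 ± 0.22 in zone 8 (SD, n = 3 each). miR-137-3p and miR-149-5p were each detected on 10 of the 12 arrays of zones 5 to 8 and on none of zones 1 to 4. Against the lowest detected signals of the zone 1 arrays they were 5.10-fold and 2.67-fold higher in zone 8.

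**Figure D1:**
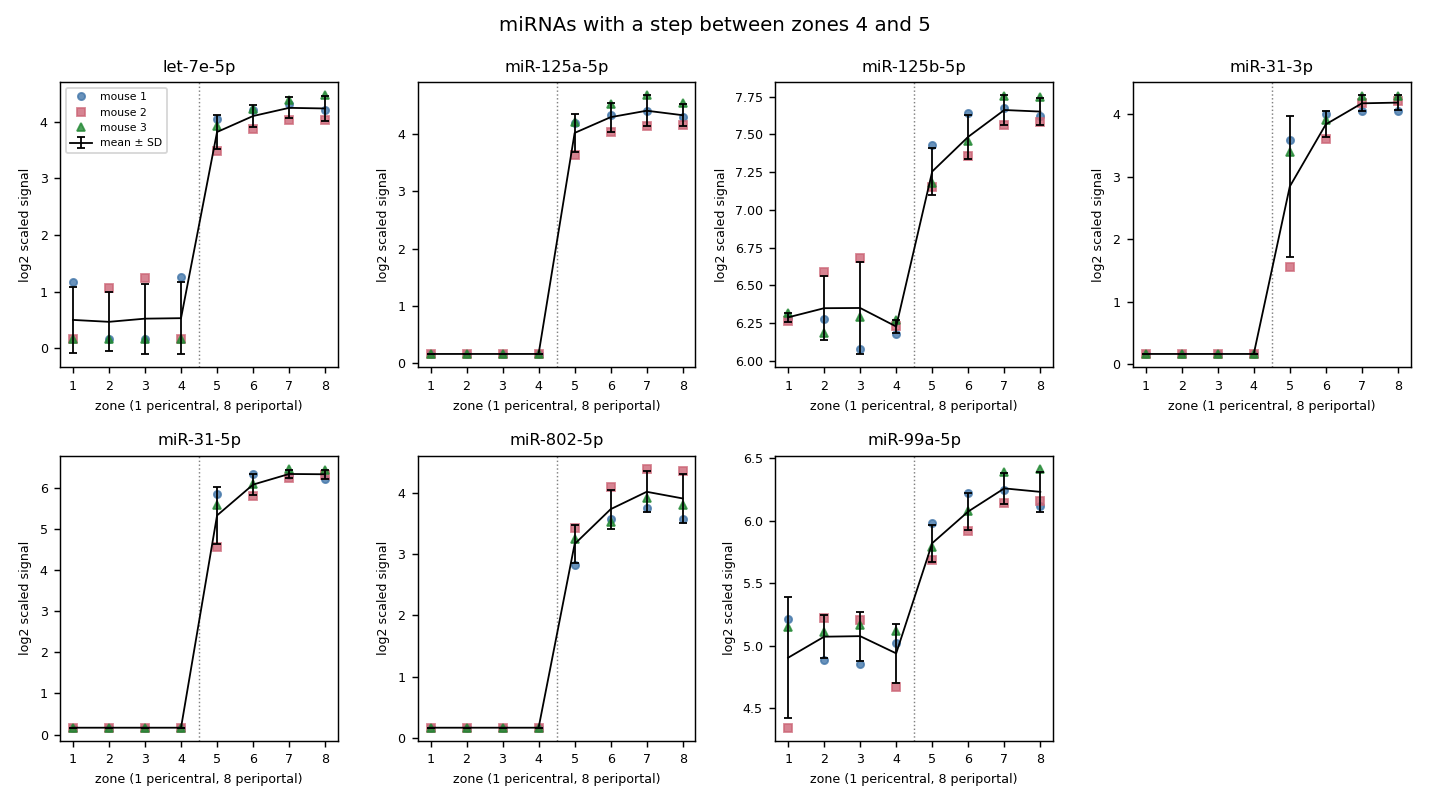
Log2 scaled signal (vertical axis) against zone (horizontal axis, 1 pericentral to 8 periportal) for 7 miRNAs; points are single arrays by mouse, the line joins the zone means, the bars are SDs (n = 3) and the dotted line marks the change of slide row between zones 4 and 5. miR-31-5p, miR-31-3p, miR-125a-5p and miR-802-5p lie at the floor of 0.17 in zones 1 to 4 and above it on all 12 arrays of zones 5 to 8.

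Of the miRNAs present along the whole axis, miR-125b-5p, miR-99a-5p and miR-100-5p rose most. The fitted change from zone 1 to zone 8 was 1.71 ± 0.19 log2 units (SE) for miR-125b-5p, 1.59 ± 0.19 for miR-99a-5p and 1.66 ± 0.27 for miR-100-5p, with limma adjusted p of 2.58e-07, 8.86e-07 and 8.09e-05. For miR-125b-5p and miR-99a-5p a line does not describe the profile, since both stepped up between zones 4 and 5. Within zones 1 to 4 the slope of miR-125b-5p was -0.0181 per zone (mouse as a block). Their fitted changes are larger than the measured differences between zones 8 and 1 given below. Of 11 hepatocyte-abundant miRNAs 5 rose. miR-122-5p, the dominant miRNA of hepatocytes, rose by 0.72 ± 0.13 (limma adjusted p = 0.000159), miR-21a-5p by 1.17 ± 0.24 and miR-148a-3p by 0.68 ± 0.16. miR-30a-5p rose by 0.83 ± 0.11 and miR-30a-3p, the other arm of its precursor, by 0.94 ± 0.14. miR-195a-3p, detected on 8 arrays, rose by 1.47 ± 0.38, and miR-3473f, detected on 10 arrays, by 1.44 ± 0.44. miR-23a-3p, miR-345-5p and miR-221-3p rose by 0.85 ± 0.15, 0.80 ± 0.14 and 0.65 ± 0.13.

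The falling miRNAs changed less than the strongest rising ones. miR-3472 fell by 2.32 ± 0.62 log2 units (SE) from zone 1 to zone 8 and miR-721 by 1.56 ± 0.44, with limma adjusted p of 0.0104 and 0.0156. miR-3535 fell by 1.01 ± 0.18 (adjusted p = 0.000243) and miR-709 fell by 0.91 ± 0.21. miR-17-3p, from the miR-17 to miR-92 cluster, fell by 0.80 ± 0.24. miR-3620-5p, miR-5112 and miR-3069-3p had fitted changes of -0.79 ± 0.24, -0.78 ± 0.27 and -0.77 ± 0.26. miR-7036a-5p, miR-7011-5p, miR-320-3p and miR-6769b-5p had changes of -0.70 ± 0.16, -0.69 ± 0.19, -0.67 ± 0.21 and -0.64 ± 0.14. miR-185-5p fell by 0.64 ± 0.14 and miR-107-3p, a miRNA known to act on insulin sensitivity, fell by 0.45 ± 0.13.

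**Figure D2:**
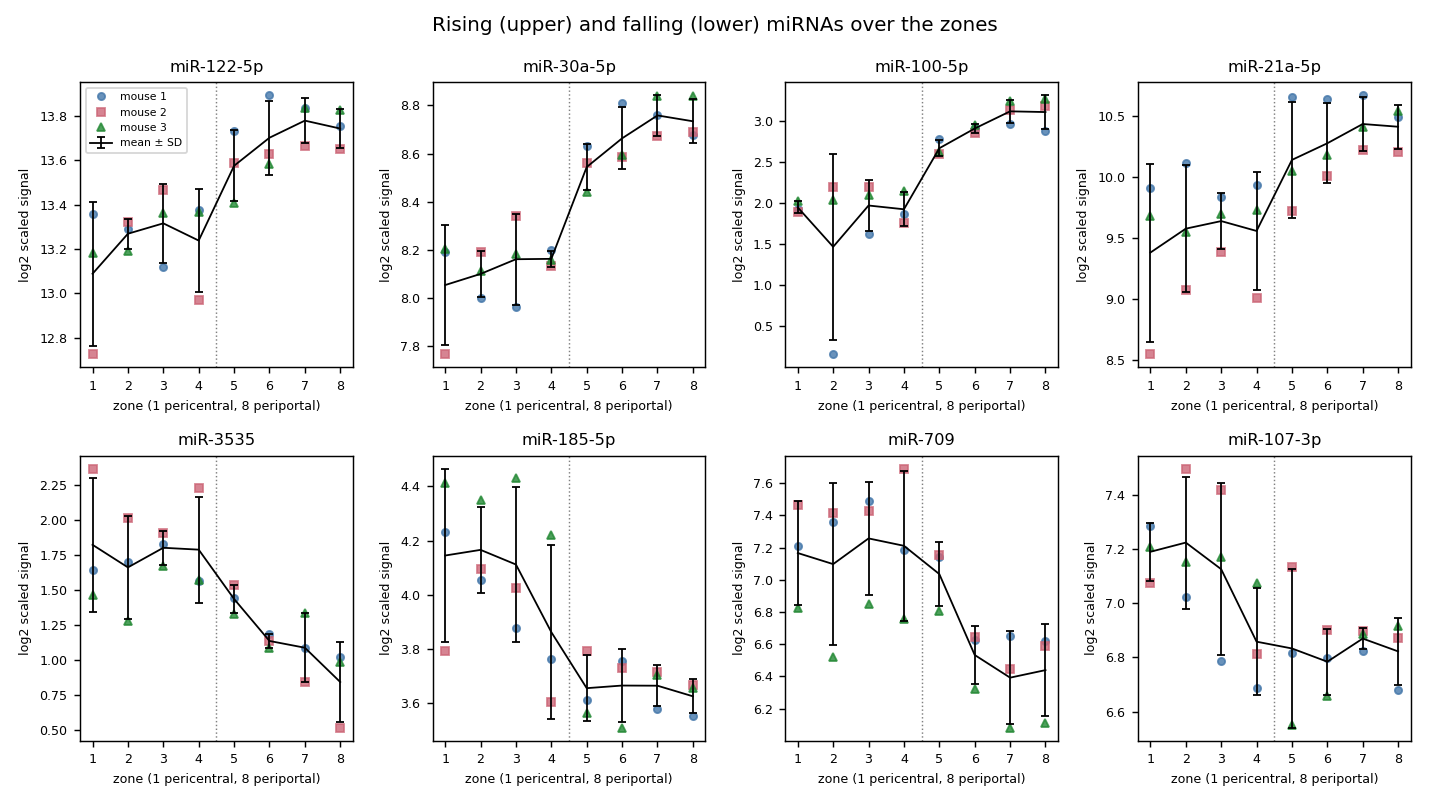
Log2 scaled signal (vertical axis) against zone (horizontal axis) for 4 rising miRNAs in the upper panels and 4 falling miRNAs in the lower panels; points are single arrays by mouse, lines join zone means and bars are SDs (n = 3). miR-122-5p rose by 0.72 and miR-3535 fell by 1.01 log2 units in the fit over the 8 zones; the vertical axes do not start at 0.

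In all, 35 miRNAs rose and 22 fell among 339 tested, with 34 of the 35 and all 22 having a slope of that sign in each of the 3 mice. With mouse as a block 49 rose and 56 fell, and the 35 and the 22 were among them. The split depended on scaling: 36 rose and 3 fell without scaling, and 44 and 6 with scaling to the summed signal, while the median fitted change of all tested miRNAs moved from -0.10 to 0.10 and 0.04. With slide row as a further term beside the mouse block no miRNA rose or fell, with 1 slope per mouse 12 rose and 0 fell, and without mouse 1 or mouse 3 the falling count was 9 or 13.

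**Figure D3:**
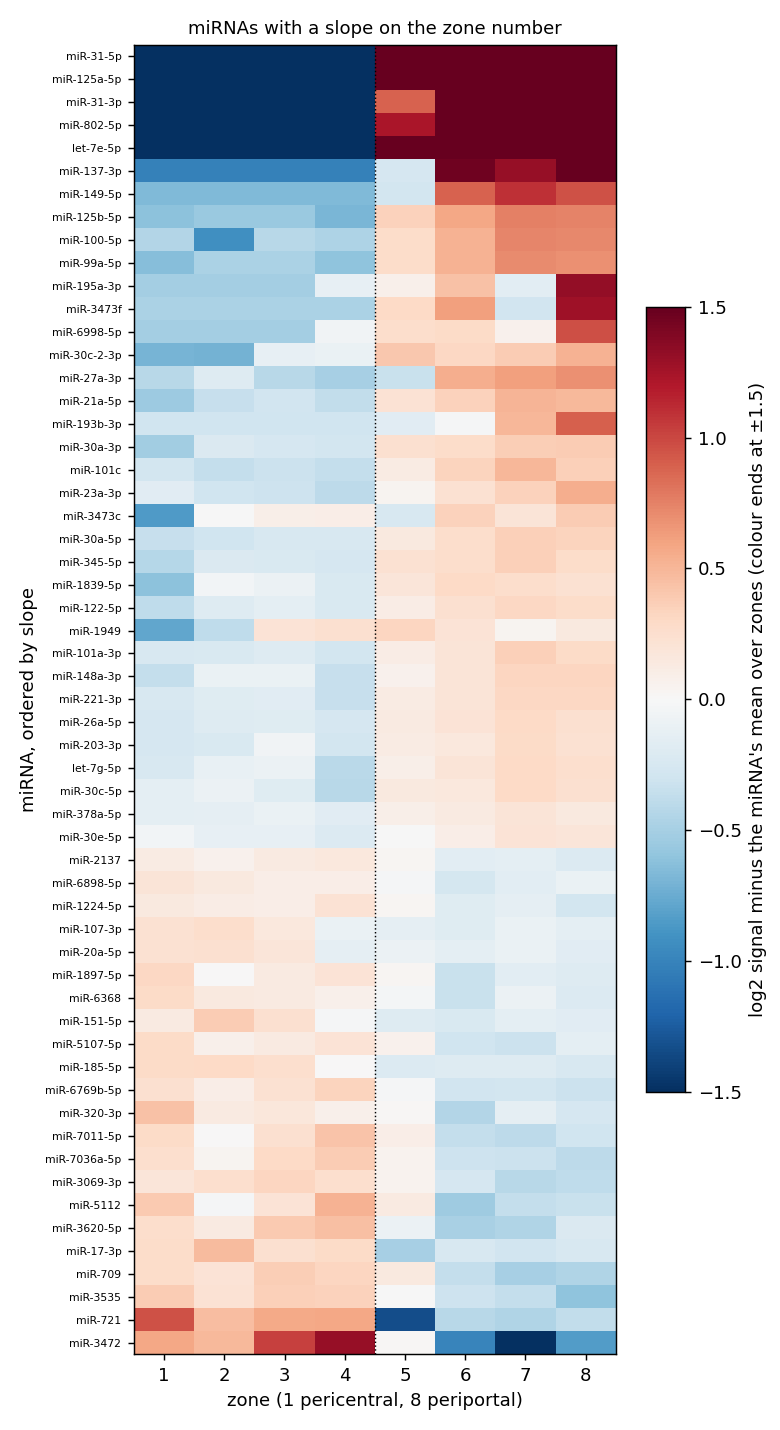
Zone means of the 57 miRNAs with a slope past the threshold, as log2 signal minus each miRNA's mean over the zones (colour, ending at 1.5 either way), by zone (horizontal axis) and ordered by slope (vertical axis); the dotted line marks the change of slide row. The upper 35 rose and the lower 22 fell, and with scaling to the summed signal 6 fell.

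The rising miRNAs changed most between zones 4 and 5, with a median difference of 0.47 log2 units, while the falling miRNAs had median differences of -0.20 between zones 4 and 5 and -0.30 between zones 5 and 6. In a fit with a step between zones 4 and 5 beside the slope, a test chosen after the data were seen, 7 miRNAs stepped up: miR-31-5p by 5.19 ± 0.27 log2 units (SE, mouse as a block), miR-125a-5p by 3.89 ± 0.15, let-7e-5p by 3.29 ± 0.33, miR-802-5p by 3.04 ± 0.22, miR-31-3p by 2.72 ± 0.39, miR-125b-5p by 0.97 ± 0.17 and miR-99a-5p by 0.79 ± 0.19. The first 5 of these contain values at the floor in zones 1 to 4, so their steps are not bounds. No miRNA stepped down in limma, against 12 at an unadjusted p under 0.05. Between neighbouring zones, 7 miRNAs were higher and 1 lower in zone 5 than in zone 4, 1 was higher in zone 6 than in zone 5, and 0 differed in the other 5 comparisons (limma, mouse as a block). All 7 stepped miRNAs also rose within zones 5 to 8 when adjusted over these 7 alone, with miR-31-5p rising by 0.33 ± 0.09 and miR-802-5p by 0.25 ± 0.06 per zone, while none passed over all 339 miRNAs. Without mouse 1 the number stepping up was 4.

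The moderated F test over the 8 zones asked for differences of any shape, and called 18 miRNAs, 16 rising and 2 falling in the slope. They included miR-31-5p (adjusted p = 9.76e-16), miR-125a-5p, miR-802-5p, miR-31-3p and let-7e-5p, and the falling miR-7036a-5p and miR-721. With mouse as a block the count was 31, without scaling it was 9, and without mouse 1 or mouse 3 it was 11 or 10.

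The ends of the axis were compared directly. In zone 8 against zone 1, 16 miRNAs were higher and 2 lower, and all 18 had also passed the slope test. Beside the miRNAs not detected in zone 1, miR-125b-5p was 2.57-fold higher in zone 8 (log2 difference 1.36 ± 0.16, SE), miR-99a-5p 2.51-fold, miR-30a-3p 1.86-fold and miR-122-5p 1.58-fold (limma adjusted p = 0.0285). The lower miRNAs were miR-3535, with a difference of -0.98 ± 0.24 (limma adjusted p = 0.0197), and miR-7036a-5p, with -0.64 ± 0.18 (adjusted p = 0.0461). With mouse as a block 26 were higher and 7 lower. Without scaling, with scaling to the summed signal, and without mouse 1 or mouse 3, 0 were lower, and without mouse 2 it was 1.

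A quadratic term asked for miRNAs that peak or dip in the middle of the lobule. No miRNA passed in either direction in limma, with or without the mouse block. At an unadjusted p under 0.05, 1 miRNA peaked and 6 dipped.

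Among the lists fixed before the data were examined, the hepatocyte-abundant miRNAs ranked towards rising slopes. Of 11 tested, 5 rose, 0 fell and 6 did not pass, 2 of them with negative slopes (miR-22-3p and miR-101b-3p), and 8 rose when adjusted over the list alone (camera adjusted p = 0.00112). miR-122-5p, miR-21a-5p, miR-26a-5p, miR-101a-3p and miR-148a-3p were the 5, while miR-192-5p had a fitted change of 0.38 ± 0.16 and did not pass. The miR-30 family had 5 of 8 rising, and 7 adjusted over the list alone (camera adjusted p = 3.97e-05): miR-30a-5p, miR-30a-3p, miR-30c-2-3p, miR-30c-5p and miR-30e-5p. In the let-7 family 2 of 9 rose, let-7e-5p and let-7g-5p, with 2 adjusted over the list alone and all 9 slopes above 0 (camera adjusted p = 0.0206), although with quantile normalization let-7c-5p fell, with a slope of -0.04 per zone (limma adjusted p = 0.0389). The miR-17 to miR-92 clusters, known for roles in proliferation, had 2 of 9 falling, miR-17-3p and miR-20a-5p, and 5 adjusted over the list alone (camera adjusted p = 0.0205). Among 4 hypoxia-associated miRNAs 2 rose, miR-21a-5p and miR-193b-3p, and 3 adjusted over the list alone (camera adjusted p = 0.0467), while miR-210-3p, the miRNA best known for induction by hypoxia, had a fitted change of -0.48 ± 0.47. Of 9 cholesterol and lipid miRNAs 4 rose and 1 fell, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.0205): miR-802-5p, miR-122-5p, miR-148a-3p and miR-30c-5p rose and miR-185-5p fell. None of these 6 lists held with an estimated correlation: the miR-30 family had adjusted p = 0.384 with an estimated correlation, the hypoxia list 0.418, the lipid list 0.423, the hepatocyte list 0.509, and the let-7 and miR-17 to miR-92 lists 0.511 each. All 6 passed in fry, with adjusted p from 8.35e-05 (miR-30 family) to 0.0347 (let-7 family). fry asks whether the members change at all, and not whether they rank beyond other miRNAs as camera does. Its passes therefore do not offset the loss with an estimated correlation. The estimates for these 6 lists ran from 0.16 (hypoxia list) to 0.72 (let-7 family), against the preset 0.01. With quantile normalization 1 list held, the miR-30 family, and the hepatocyte list had camera adjusted p = 0.186. The miR-17 to miR-92 and hypoxia lists were also lost without scaling (camera adjusted p = 0.151 and 0.0517) and with the summed signal (0.103 and 0.0831). With mouse as a block, over all tested miRNAs, 7 of the hepatocyte-abundant miRNAs, 7 of the miR-30 family and 6 of the lipid miRNAs rose. In that fit 5 of the miR-17 to miR-92 clusters and 1 lipid miRNA fell, and 2 rose in each of the let-7 and hypoxia lists.

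The other lists did not pass camera at the preset correlation with the scaling and filter used here and no block. In fry the insulin and glucose list passed (adjusted p = 0.0096) and the rest did not. Of 9 insulin and glucose miRNAs 3 rose, miR-802-5p, miR-26a-5p and miR-378a-5p, and 1 fell, miR-107-3p, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.0515). With mouse as a block, over all tested miRNAs, 5 of them rose and 1 fell. That list passed with mouse as a block (0.0455), without scaling (0.0166), with the summed signal (0.0282) and with miRNAs detected on at least 1 array (0.0251), and did not with an estimated correlation (0.511), quantile normalization (0.217), a floor 4 times lower (0.0530) or miRNAs detected on all 24 arrays (0.148). The miR-23, miR-27 and miR-24 clusters had 2 of 5 rising, miR-23a-3p and miR-27a-3p, and 2 adjusted over the list alone (camera adjusted p = 0.355), while miR-23b-3p had a change of -0.22 ± 0.15. The miR-103, miR-107 and miR-26 families had 1 of 4 rising and 1 falling, and 2 and 1 adjusted over the list alone (adjusted p = 0.711). The miR-29 family had 0 of 4 past the test and 1 rising adjusted over the list alone (adjusted p = 0.439), with miR-29a-3p (fitted change 0.38 ± 0.14) passing over all miRNAs with mouse as a block (limma adjusted p = 0.0273), and the miR-15, miR-16 and miR-195 family 0 of 4 and 0 (adjusted p = 0.355). In the Dlk1-Dio3 imprinted cluster 0 of 3 passed, and 0 adjusted over the list alone (adjusted p = 0.812), with median and mean slopes of opposite sign, 0.01 and -0.09. miR-376b-3p, detected on 12 arrays, had a fitted change of -2.40 ± 1.08 and limma adjusted p = 0.134, and with mouse as a block it passed downward (adjusted p = 0.00236). Most members of this cluster were too rarely detected to be tested: 9 of the 12 detected, among them miR-127-3p, miR-379-5p, miR-434-3p and miR-136-5p, were detected on 2 to 4 arrays of zones 1 to 4, mostly of mouse 3, and on none of zones 5 to 8. With miRNAs detected on at least 1 array the list passed towards falling slopes (camera adjusted p = 0.0032). miR-34a-5p, the 1 tested member of the miR-34 family, had a fitted change of 0.25 ± 0.18 and did not pass.

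Of 33 miRNAs on the array listed for other liver cells, the miR-200 family included, 2 were detected on any array. None of 7 leukocyte and Kupffer cell miRNAs, 9 stellate cell and fibroblast miRNAs and 5 erythroid miRNAs on the array was detected on any array, nor were any of 3 miRNAs of the miR-183, miR-96 and miR-182 cluster or 6 of the miR-181 family. Of 7 miRNAs of the miR-200 family, known from biliary and other epithelium, 1 was detected, on 1 array. Of 5 endothelial miRNAs miR-126a-3p alone was detected, on 7 of 12 arrays of zones 1 to 4 and 9 of 12 of zones 5 to 8, with a fitted change of 0.16 ± 0.74.

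A few miRNAs held most of the signal, which does not rank their amounts, since the signal per molecule differs between probes. miR-6366 held 32.8% ± 3.96 of an array's summed signal (SD over 24 arrays), miR-3963 26.6% ± 2.96, miR-122-5p 12.9% ± 3.78, miR-5100 4.57% ± 0.460 and miR-3968 4.25% ± 0.858. The share of miR-122-5p was 8.87% ± 1.96 in zone 1 and 16.3% ± 4.66 in zone 8 (SD, n = 3), and that of miR-6366 was 36.0% ± 0.760 and 29.2% ± 5.38. These shares were not tested.

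Slopes of the 3 mice were compared across miRNAs, which are not independent replicates. Of 339 miRNAs 196 (57.8%) had the same sign in all 3 mice, against 25% by chance, and Pearson correlations between mice were 0.633, 0.825 and 0.685 (Spearman 0.352, 0.621 and 0.418). Without the 7 rising miRNAs undetected in zones 1 to 4, which include miR-31-5p and miR-802-5p, the Pearson values were 0.350, 0.638 and 0.445. In a principal component analysis, component 1 (37.2% of the variance) set mouse 2 apart and component 2 (22.1%) separated zones 1 to 4 from zones 5 to 8 without overlap. These groups are also the first and second slide rows on all 3 slides. An effect of slide position would therefore recur in each mouse. Neither the shared signs nor component 2 can tell it apart from zone.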

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

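The slide-row, other-cell, separate-run and both step-count tests and the second set of draws in this part were chosen after the step was seen. Control sequences on the arrays lie outside the miRNA comparisons, and 5 of them gave a signal on some arrays and not on others. The sequences dmr_285, dmr_3, dmr_31a and dmr_6 were detected on 16 arrays each, all 8 of mouse 1 and all 8 of mouse 2 and none of mouse 3, and miRNABrightCorner30 on 22 arrays. The hur_1, hur_2, hur_4, hur_6 and mr_1 controls were detected on all 24.

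The step between zones 4 and 5, led by miR-31-5p, miR-125a-5p, miR-802-5p and let-7e-5p, falls where the slide row changes. A difference in hybridization or scanning between rows would move the control sequences too. On single slides the row differences of the 10 controls detected on at least 16 arrays had a median size of 0.143 log2 units. They reached 0.50 upward (mouse 1) and -0.83 downward (mouse 2), both for the bright corner, and had no mouse 3 value for 4 of them. On the slide of mouse 2 every control moved downward, among them mr_1 by -0.69 and hur_2 by -0.58. Against this, the 5 stepped miRNAs not detected on all arrays of zones 1 to 4 differed by at least 3.20 upward on each slide. For miR-125b-5p and miR-99a-5p the row difference was at least 0.972, which includes their slope along the zones. Beside the slope the step of miR-99a-5p was 0.79 ± 0.19, within the size of the control differences, so the controls cannot decide for these 2 miRNAs. The miRNAs were picked for their step and the controls were not. RNA of leukocytes, stellate or erythroid cells would bring the miRNAs abundant in those cells, and the 21 listed had 0 detections in 252 array values of zones 5 to 8, with CD45 cells also removed by the sort. RNA of endothelial or biliary cells cannot be told apart from zonation, although CD31 cells were removed, since of their lists 2 members were detected, miR-200b-3p on 1 array and miR-126a-3p on 16, and the upper 95% end of the step of miR-126a-3p was 0.44 with the mouse block and 1.73 without it, against a smallest step of 0.79. Handling of zones 1 to 4 and zones 5 to 8 in separate runs cannot be told apart from zonation either, since row and zone coincide; 7 of the 7 miRNAs rose within zones 5 to 8 when adjusted over these 7 alone and none over all 339, so this decides nothing, and a difference between periportal and pericentral hepatocytes stays open as a hypothesis.

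For the counts, zone labels were permuted within mice in 100 draws, the real order included. For miRNAs varying over the zones 1 draw, the real one, gave as many (18, highest other 10), as for rising (35, highest other 0) and falling (22, highest other 0) miRNAs. Each share lies under 0.05, so chance is unlikely for these counts. In a second set of 100 draws the real order was again the 1 draw as large for each, with highest other counts of 8, 0 and 0. The highest other count depends on the draw, since 100 draws sample few of the possible orders. A set drawn earlier with other random numbers came close to the real count for miRNAs varying over the zones, though still under it. The margin for that count is therefore narrow. Earlier sets also reached a higher one for the step down. Since zones 4 and 5 were picked for the step, each draw was given its best of the 7 cuts between neighbouring zones. Of the 100 draws 2 gave as many steps up as the real order (7, highest other 15), and 4 in the second set (highest other 12). These shares lie close to 0.05 and single orders call more steps than the real one. Chance is therefore not firmly excluded for the number of steps. The draws count steps and do not test single miRNAs. miR-31-5p, miR-31-3p, miR-125a-5p and miR-802-5p were detected on 0 of 12 arrays of zones 1 to 4 and all 12 of zones 5 to 8. Their row difference was at least 3.2 log2 units upward on each slide. These values argue against chance for these 4 miRNAs, though they were picked for their step. The values do not tell zone apart from position on the slide. For the step down and the mid-lobule peak and trough the real count was 0, which all 100 draws reach, so these draws show nothing about them; the highest other was 1 for the step down and 0 for the peak and trough, and 0, 1 and 0 in the second set. The 6 arrays of zones 1 and 8 allow 10 splits, too few for a share under 0.05: 12 miRNAs were higher in the real split against 0 in the highest other (1 split as large), and 0 were lower against 0 (10 splits as large).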

How the results depend on the processing

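The slide-row and other alternatives were fixed before the data were examined, except the fits within zones 1 to 4 or zones 5 to 8, the summed signal with the mouse block, the hur scaling and the fits with a step, which were chosen after the data were seen; where no reason is given, the cause was not tested. The rising count stayed within 1.5 times of 35 under every scaling, filter, floor and left-out zone or mouse, and the peak count was 0 in the fits that counted it, which leave out the hur scaling, the summed signal with the block, the 6 arrays of zones 1 and 8 and the fits within zones 1 to 4 or zones 5 to 8. Without scaling (the 75th percentile over all miRNAs) 9 miRNAs varied over the zones, 3 fell and 0 were lower in zone 8; with the summed signal 6 fell and 0 were lower; with the hur controls 4 fell. Quantile normalization left 1 list, and let-7c-5p and miR-29c-3p turned to falling calls, with slopes of -0.0374 and -0.0385 (limma adjusted p = 0.0389 and 0.0231). Testing only miRNAs detected on all 24 arrays, which drops most of the stepped miRNAs, gave 9 higher in zone 8, 1 step up and 2 lists, and a filter at 1 array gave 1 trough. The let-7, lipid and miR-17 to miR-92 lists were lost at 24 arrays (camera adjusted p = 0.0892, 0.112 and 0.124), and the Dlk1-Dio3 list passed at 1 array (0.0032), where more of its members enter. With the mouse block, which pairs the arrays of an animal, 31 varied, 56 fell, 26 were higher and 7 lower in zone 8, and it ended no rising or falling call; with the summed signal and the block 61 rose. With the block and slide row 0 rose and 0 fell, in a fit where row and zone largely coincide, and slopes turned to 0.0912 for miR-721, 0.0268 for miR-17-3p, 0.0214 for miR-3620-5p and -0.0245 for miR-30c-5p. One value per mouse, with 3 values per miRNA, gave 12 rising and 0 falling, and the 6 arrays of zones 1 and 8 alone gave 0 lower. Without each mouse in turn 10 to 12 varied, 9 to 25 fell, 24 to 30 rose, 11 to 13 were higher and 0 to 1 lower in zone 8, 4 to 7 stepped up and 0 to 1 stepped down. The falling count was 14, 12, 10 and 13 without zone 3, 6, 7 or 8. Within zones 1 to 4 with the block, on 12 arrays, 6 rose and 1 fell, among them 1 of the 35 rising and 0 of the 22 falling miRNAs, 17 of the 35 had a slope above 0, and slopes that turned were -0.0181 for miR-125b-5p, 0.271 for miR-3472, 0.00361 for miR-3535, 0.0294 for miR-709, 0.0788 for miR-3620-5p, 0.0599 for miR-5112, 0.0295 for miR-3069-3p, 0.0643 for miR-7036a-5p, 0.0651 for miR-7011-5p, 0.0436 for miR-6769b-5p, -0.0467 for let-7g-5p, -0.0904 for miR-30c-5p, -0.0674 for miR-23a-3p, -0.0488 for miR-27a-3p and -0.00252 for miR-378a-5p. Of the 35, 7 were undetected on all arrays of zones 1 to 4, so their slope there was 0. Slopes of 11 of the 22 falling miRNAs were below 0 there. Within zones 5 to 8 with the block 0 rose and 0 fell, and miR-721, miR-17-3p and miR-107-3p turned to 0.286, 0.0739 and 0.00531. In zones 5 to 8, 34 of the 35 rising miRNAs had a slope above 0 and 18 of the 22 falling ones below 0. The 35 and the 22 were picked on arrays that include these. Signals near the floor of 1.12 limit what can be measured for dim miRNAs such as miR-193b-3p, detected on 7 arrays.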

Other observations

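All tests in this part except that of precursor arms were chosen after the slopes were seen. The falling and the rising miRNAs differed in their miRBase numbers. Of the 22 falling miRNAs 14 had a miRBase number of 1000 or more, such as miR-3472, miR-3535 and miR-7036a-5p, against 5 of the 35 rising and 165 of the 339 tested. The rising miRNAs lay further from the share of all tested than the falling ones did, and neither group was tested against all 339. The difference between falling and rising miRNAs had a two-sided p of 0.000341 in Fisher's exact test over miRNAs, which are not independent. Scaling may carry part of it: 4 of the 22 falling miRNAs passed with scaling to the summed signal and 3 without scaling, while all 22 kept a negative slope and their median fitted change moved from -0.66 to -0.49 and -0.43. Scaling and a fall of these miRNAs cannot be told apart here, and no biological explanation was tested.

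The arms of a precursor come from 1 transcript, and a hypothesis is that they share the zone slope. Over 31 pairs of arms the Pearson correlation was 0.763, and a share of 0.0038 of 10000 random pairings was as high (Spearman 0.350, share 0.0295). It rested on miR-31: without that pair it was 0.209 with a share of 0.108, and 17 of the 31 pairs had slopes of the same sign, which 0.468 of the pairings reached.

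A related hypothesis is that miRNAs whose genes lie within 10 kb share the slope. Over 81 pairs the Pearson correlation was 0.540, with a share of 0.0004 of 10000 shuffles as high and 56 pairs of the same sign. Most of it came from let-7e-5p and miR-125a-5p: without that pair it was 0.189, with a share of 0.0253. The pairs are not independent, since the 81 pairs were made from 75 miRNAs. Many join miR-466, miR-467 and miR-669 miRNAs or members of 1 family such as let-7. The shuffles did not allow for this. The outcome depended on how names were matched to genes. A first match, by synonym alone, found 299 of the 339 miRNAs and missed miR-125a, and over its 24 pairs the correlation was 0.246 with a share of 0.084, within the range of the shuffles. The match was widened to gene symbols after that value was seen.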
